A study of Pseudomonas chlororaphis subsp. aureofaciens 30-84 with 4 samples.

How the data were processed

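The data are transcript levels from 4 bacterial cultures, 2 of wild-type Pseudomonas chlororaphis 30-84 and 2 of a strain labelled hfq mutant. Per the labels, replicates came from single colonies on separate plates and were grown in 1.5 ml of AB minimal medium with 2% casamino acids, at 28 °C, to an optical density at 600 nm of about 1.8. The labels describe rRNA depletion, fragmentation of 300 ng of RNA to about 200 bases, strand-specific libraries selected at 200 to 300 bases and paired-end sequencing on a SOLiD instrument. Another of the labels' protocols names an Illumina library kit instead, and the series' design text names a different mutant (ZN) where every sample label names hfq. The samples were grouped by their genotype labels. No label names a shared day or batch. P-values rest on the spread between these 4 libraries, pooled over genes of similar level. On the deposited values that pooled spread alone was used, so a gene's own spread did not count. After median-ratio scaling, described below, a gene's own spread counted in part.

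The deposited table gives 1 RPKM value per gene and library, that is, reads per kilobase of gene scaled to the total reads of the library, as computed by the authors per the file headers. The aligner, counting tool and genome build are not given in the sources used here, so no coordinates are printed. Genes are named by the table's own symbols, held by 2101 of 5961 entries, and by locus tag otherwise; 5861 locus tags matched the RefSeq gene table (assembly ASM28191v1), which supplied gene lengths and neighbours. The locus tag of tssJ2 stands on 2 entries, which were kept apart, and 1 entry without a product, ssrA, is a transfer-messenger RNA in the gene table. Reads shared between near-identical copies, such as the rRNA genes, may have been split or dropped by the authors' counting, so values of single rRNA genes are uncertain.

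RPKM multiplied by gene length fell on multiples of 1 step per library. These steps gave 93.5 to 93.7% whole reads within a tolerance of 0.05 read, and totals between 12507603 and 19903684 reads. These totals included rRNA reads, so a library with much rRNA has lower RPKM for every other gene. Median reads per recovered gene were 585 and 515 in wild type and 185 and 680 in the hfq mutant libraries, so hfq mutant replicate 1 carries the largest counting error. 12 genes were listed at 0 in a library. The median 95% interval of a log2 fold change was ± 1.53 on the values as deposited and ± 0.31 after median-ratio scaling.

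The strains were compared with limma 3.58.1 in R 4.3.3 on log2(RPKM + 1), a pseudocount of 1 that understates the change of low genes, with a mean-dependent prior. Genes with a mean RPKM of at least 1 were tested two-sided, and p-values were adjusted by Benjamini-Hochberg over all 5960 genes and called below 0.05. The comparison planned as the main one uses the values as deposited and no replicate block. Median-ratio scaling sets the median log ratio of each library to the mean library to 0 and was among the alternatives listed before the data were examined. The choice to lead the account of genes and lists with it, and to apply the rule for named genes to it, was made after the rRNA shares and the results had been seen. Its log2 factors were 0.45 and 0.23 for wild type and -0.97 and 0.29 for the hfq mutant libraries. It assumes that the median gene does not differ between strains. The other scalings were quantile normalization, removal of rRNA and tRNA genes with rescaling to the same total, and scaling to reads outside rRNA genes, the last added after the data were seen.

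Before the data were examined, 23 gene lists were fixed by symbol or product text: the hfq locus, phenazine biosynthesis, quorum sensing, the Gac-Rsm pathway, other exoproducts, siderophore and iron uptake, flagella and chemotaxis, type VI secretion, pili, exopolysaccharide and biofilm, amino acid catabolism, carbon catabolite control, amino acid and peptide transport, ribosomal proteins, chaperones and proteases, oxidative stress, the TCA cycle and respiration, low-oxygen respiration, multidrug efflux, outer membrane and cell envelope, prophage and tailocin, transposase and mobile elements, and type III secretion. Accidental text matches, 21 of 943, were removed from 9 lists after fold changes had been seen. This left type III secretion with 0 members, so 22 lists of at least 3 members were tested. Each list was tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry, each adjusted by Benjamini-Hochberg over the 22 lists. The preset correlation gave 8 lists past 0.05 as deposited and 10 after median-ratio scaling, the 8 among them. With an estimated correlation 0 passed on either scale. Fry, which tests whether the members of a list move one way on balance, passed 14 lists after median-ratio scaling and 0 as deposited. Of the lists past camera after this scaling, only phenazine biosynthesis did not pass fry (fry adjusted p = 0.0524). Fry also passed lists that camera did not. These were carbon catabolite control, exopolysaccharide and biofilm, low-oxygen respiration, multidrug efflux, and outer membrane and cell envelope.

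Genes were named by a rule fixed before the data were examined: hfq and its list; the 12 largest changes in each direction among called genes with a known product and with both hfq mutant libraries beyond both wild-type libraries; the largest change in each direction without a known product; and up to 4 called members of each list with the smallest p. Any further gene was named after its values were seen. These were rrf and the other genes called on the deposited values, and the members that moved against their list. The remaining phz genes, iopA and Pchl3084_0233 were also named in this way.

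The procedure was tested on simulated data for the comparison of hfq mutant with wild type over 5960 genes, with 100 genes changed by 1 and 100 by 2 on the log2 scale. As deposited it recovered 0% and 1% of them, and after median-ratio scaling 41% and 82%, with 0 false calls among 123. The simulation changed few genes, as many up as down, and let genes vary independently, so the assumption of median-ratio scaling held by design. Its false calls therefore do not cover errors from the choice of scaling or errors shared by many genes. Both replicate pairs differed by more than sampling noise, with a mean chi-square per gene of 7.72 for wild type and 15.4 for hfq mutant, and were kept as separate samples. Libraries of the strains did not overlap for 45.8% of genes as deposited, with the hfq mutant higher for 55 and lower for 2678. After median-ratio scaling they did not overlap for 73.9%, higher for 2171 and lower for 2237; chance gives 33.3%. Other alternatives were pseudocounts of 0.1 and 5, no filter and a mean RPKM of at least 10, limma without the trend or with a robust prior, a replicate block, each library left out in turn, and limma's count model on the 5446 tested genes with recovered reads. Tables were handled in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures drawn with matplotlib 3.10.9.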

Results

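Pseudomonas chlororaphis 30-84 is a root-colonizing bacterium that makes phenazines, coloured antibiotics that act against fungi. Hfq is an RNA chaperone that helps small regulatory RNAs pair with messenger RNAs. Transcript levels were measured by RNA sequencing in 2 wild-type libraries and 2 libraries labelled hfq mutant, and the comparison asks which genes differ in level between the strains. The cultures were grown at 28 °C to an optical density of about 1.8 in AB minimal medium with 2% casamino acids. The table listed 5961 genes, of which 5960 had a mean of at least 1 RPKM and were tested. The RPKM steps implied 15140519 and 15289977 reads in wild-type replicates 1 and 2, and 12507603 and 19903684 reads in hfq mutant replicates 1 and 2.

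The libraries differed in ribosomal RNA. Reads in the 19 rRNA genes made up 3.60% of wild-type replicate 1 (95% Wilson interval 3.59 to 3.60) and 13.0% of wild-type replicate 2 (13.0 to 13.0). They made up 58.3% of hfq mutant replicate 1 (58.2 to 58.3) and 1.01% of hfq mutant replicate 2 (1.00 to 1.01). These intervals cover counting error only. The median gene stood at 47.7 and 41.9 RPKM in the wild-type libraries, at 18.6 RPKM in hfq mutant replicate 1 and at 42.7 RPKM in hfq mutant replicate 2. Across genes, log2(RPKM + 1) correlated at r = 0.995 between the wild-type libraries, at 0.972 between the libraries labelled hfq mutant and at 0.952 to 0.967 across strains, where genes are not independent replicates.

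**Figure D1:**
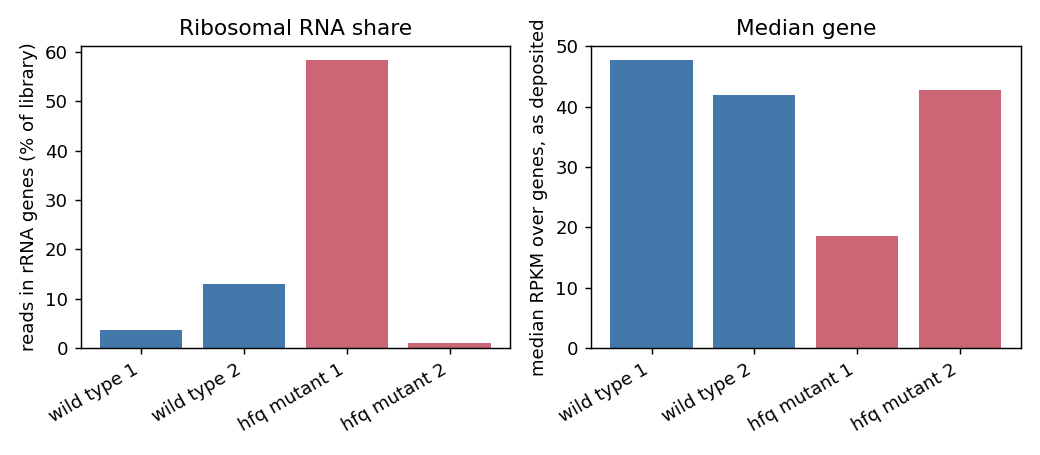
Left, the share of reads in rRNA genes (% of the library); right, the median RPKM over genes as deposited; 1 bar is 1 library, blue for wild type and red for hfq mutant, with no error bars. The rRNA share is 58.3% in hfq mutant replicate 1 and 1.01% in hfq mutant replicate 2, and the median gene is at 18.6 and 42.7 RPKM in the same libraries.

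The hfq transcript (Pchl3084_0554) was present in every library, at 2073 and 1909 RPKM in wild type and at 612 and 1647 RPKM in the libraries labelled hfq mutant. As deposited, the hfq log2 fold change was -0.99 and did not pass the test (limma, Benjamini-Hochberg adjusted p = 0.775). With the libraries scaled to their median ratio it was -0.31 ± 0.24 (95% interval, n = 2 per strain; limma, Benjamini-Hochberg adjusted p = 0.0592). It passed at -0.64 with quantile normalization (limma adjusted p = 0.0432), at -0.51 with rRNA and tRNA genes left out (limma adjusted p = 0.00259) and at -0.48 when scaled to reads outside rRNA genes (limma adjusted p = 0.0142). On the deposited values the change was -1.70 without hfq mutant replicate 2, where the median gene stood at -1.25. It was -0.27 without hfq mutant replicate 1, where the median gene stood at -0.072. Since the transcript was present at these levels, each direction below refers to libraries labelled hfq mutant. Of the 9 genes in the list of the hfq locus and related proteins, 1 rose and 1 fell after median-ratio scaling, and camera gave no shift of the list (adjusted p = 0.733). The gene that fell was miaA, a tRNA-modifying enzyme encoded beside hfq (-0.58). The gene that rose was hflK (0.32, but -0.35 as deposited). Adjusted over the list alone, 0 rose and 1 fell.

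On the values as deposited, 1 gene was called higher and 12 lower (limma, Benjamini-Hochberg adjusted p below 0.05; 19 higher and 325 lower at an unadjusted p below 0.05). The gene called higher was a 5S rRNA gene, rrf (Pchl3084_4024). It stood at 1.71 and 2.26 RPKM in wild-type replicates 1 and 2 and at 336 and 2.60 RPKM in hfq mutant replicates 1 and 2. Its call rested on hfq mutant replicate 1 and on a spread pooled over genes. After median-ratio scaling rrf was at 4.14 ± 5.96 (95% interval) and was not called (limma adjusted p = 0.218). The 12 called lower were katB, katG, pvdS, phnW, hutU and the genes Pchl3084_1964, Pchl3084_1965, Pchl3084_2900, Pchl3084_3346, Pchl3084_4035, Pchl3084_4039 and Pchl3084_5137. All 12 were also called lower after median-ratio scaling. With a replicate block, 0 genes were called in either direction on the deposited values. The deposited values placed the median gene at -0.67 on the log2 scale, and median-ratio scaling moved that median to -0.023. After this scaling 1195 genes were called higher and 846 lower, and the split depended on the scaling: 822 and 733 with quantile normalization, 691 and 1594 with rRNA and tRNA genes left out, and 707 and 1286 when scaled to reads outside rRNA genes. Under all 4 of these scalings 519 genes were called higher and 651 lower. Counts also fell when a wild-type library was left out, to 158 higher and 240 lower without replicate 1 and to 332 and 258 without replicate 2; without hfq mutant replicate 2 they were 1790 and 1465. Below, rose and fell mean a call by limma after median-ratio scaling, and values are log2 fold changes of hfq mutant over wild type on log2(RPKM + 1) with their 95% interval. On the deposited values the same genes lie lower, by about the shift of the median gene. The counts of each list below are to be read against the 1195 that rose and 846 that fell of all 5960 tested genes.

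The genes that rose most were Pchl3084_1182 (3.31 ± 0.35; limma, Benjamini-Hochberg adjusted p = 0.000354), an S-(hydroxymethyl)glutathione dehydrogenase, and its neighbour fghA (3.09 ± 0.32), an S-formylglutathione hydrolase; these enzymes act in succession in glutathione-dependent formaldehyde oxidation. Scaled RPKM of Pchl3084_1182 went from 81.4 ± 4.4 in wild type to 823.4 ± 148.0 (SD, n = 2) in the libraries labelled hfq mutant. Genes of tryptophan synthesis followed: trpE (2.74 ± 0.23; limma, Benjamini-Hochberg adjusted p = 0.000324) and trpG (2.60 ± 0.23), the subunits of anthranilate synthase, trpD (2.67 ± 0.19) and trpC (2.47 ± 0.23). The deposited RPKM of trpE were 257 and 234 in wild type and 625 and 1685 in the libraries labelled hfq mutant. aroF (Pchl3084_3497, 2.63 ± 0.22) encodes 3-deoxy-7-phosphoheptulonate synthase, the entry enzyme of aromatic amino acid synthesis. antA (2.54 ± 0.26), antB (2.49 ± 0.25) and antC (2.40 ± 0.43) encode anthranilate dioxygenase, which degrades anthranilate. The remaining genes of this set were Pchl3084_1492 (2.29 ± 0.23), a transporter of the major facilitator family, and Pchl3084_1488 (2.26 ± 0.23), a dioxygenase subunit. Pchl3084_1491, of unknown product, lies between them in the gene table and rose by 2.29 ± 0.30.

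The genes that fell most were katB (-3.03 ± 0.29; limma, Benjamini-Hochberg adjusted p = 0.000337), a catalase that breaks down hydrogen peroxide, and pvdS (-2.83 ± 0.32), the sigma factor that drives pyoverdine genes. The deposited RPKM of katB were 1950 and 1771 in wild type and 101 and 198 in the libraries labelled hfq mutant. ahpC (-2.56 ± 0.62) and ahpF (-2.48 ± 0.31), the subunits of alkyl hydroperoxide reductase, fell together with Pchl3084_5137 (-2.44 ± 0.29), an ankyrin repeat gene next to katB in the gene table. phnW (-2.76 ± 0.37), which encodes a transaminase of 2-aminoethylphosphonate breakdown, and hutU (-2.46 ± 0.36), urocanate hydratase of histidine breakdown, were also in this set. The others were the efflux pump gene Pchl3084_3346 (-2.51 ± 0.21), a lipoprotein gene, Pchl3084_4035 (-2.54 ± 0.23), an acetyltransferase gene, Pchl3084_1964 (-2.41 ± 0.20), a thioesterase gene, Pchl3084_5528 (-2.37 ± 0.22) and a monooxygenase gene, Pchl3084_4039 (-2.37 ± 0.27). Pchl3084_1965, of unknown product, fell by 2.42 on the log2 scale. Every gene of these rising and falling sets kept its call and direction under each of the 4 scalings, and its direction without any 1 of the 4 libraries. On the deposited values, which are not among these scalings, no gene of the rising set was called. Nor were ahpC, ahpF and Pchl3084_5528 of the falling set (limma adjusted p = 0.0588, 0.0527 and 0.0539). Of all 105 genes named by rule, 25 were no longer called without wild-type replicate 1 and 23 without wild-type replicate 2, among them in both cases miaA, hflK, csaR, iopB, Pchl3084_0010, gacA, groS, fliA, algR, cbrB, Pchl3084_4518 and Pchl3084_4519; rpoN was not called without wild-type replicate 1.

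**Figure D2:**
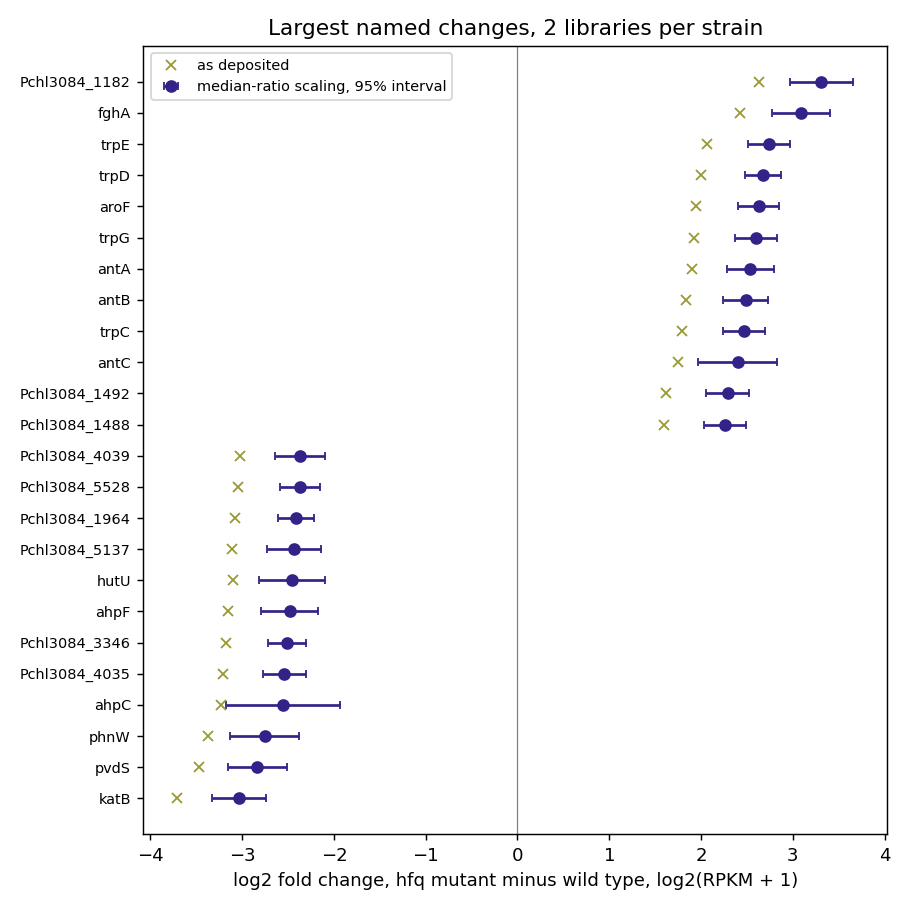
Log2 fold change of hfq mutant over wild type on log2(RPKM + 1) for the 12 named genes with the largest rise and the 12 with the largest fall, 2 libraries per strain; dots are median-ratio scaled values, bars their 95% intervals and crosses the deposited values. The rises run from 2.26 for Pchl3084_1488 to 3.31 for Pchl3084_1182, the falls from -2.37 for Pchl3084_4039 to -3.03 for katB, and every cross lies to the left of its dot.

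Of 13 members of the phenazine list, 9 fell and 0 rose (also 9 and 0 adjusted over the list alone), with a list median of -0.65. Camera gave an adjusted p = 0.000796, and an adjusted p = 0.448 with an estimated correlation. The list did not pass fry (fry adjusted p = 0.0524). phzO (-1.02 ± 0.31), phzE (-1.02 ± 0.34) and phzF (-0.93 ± 0.26), enzymes of phenazine synthesis, were among them, as was iopB (-0.60 ± 0.24), annotated as an inducer of phenazines. phzF stood at 1753 and 1737 RPKM in wild type and at 385 and 848 RPKM in the libraries labelled hfq mutant. phzA, the opening gene of the operon, was at -0.56 ± 0.56 and did not pass. Apart from iopA (-0.31) and iopB, all the falls lay in this operon (phzB to phzG and phzO). They are therefore not independent of each other. All 9 falls held under the 4 scalings. Of 8 quorum sensing genes, 1 rose and 2 fell (the same counts adjusted over the list alone), and camera gave an adjusted p = 0.319. The signal synthase gene phzI was at -0.25 ± 0.39 and its receptor gene phzR at -0.23 ± 0.30, neither past the test. csaR, the receptor gene of another signal system, fell (-1.06 ± 0.49), as did the acylase gene pvdQ (-1.43 ± 0.20), and Pchl3084_0010, a putative signal synthase gene, rose (0.88 ± 0.44). In the Gac-Rsm list, a regulatory pathway of secondary metabolism, 1 of 11 genes rose and 0 fell, and 0 passed when adjusted over the list alone; camera gave an adjusted p = 0.796. That gene was gacA, at 0.28 ± 0.20 and at -0.39 as deposited.

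Of 29 genes in the list of other exoproducts, 17 fell and 1 rose (20 and 1 adjusted over the list alone), with a median of -0.70; camera gave an adjusted p = 1.05e-05, and an adjusted p = 0.388 with an estimated correlation. The alkaline protease gene aprA fell by 1.74 on the log2 scale, and prnA (-1.18), prnB (-1.04) and prnC (-1.04), which make the antifungal pyrrolnitrin, fell too. The member that rose was hcnA of hydrogen cyanide synthesis, at 0.38 and at -0.30 as deposited; 13 of the 17 falls held under the 4 scalings. Of 95 siderophore and iron uptake genes, 40 fell and 3 rose (42 and 3 adjusted over the list alone), with a median of -0.53; camera gave an adjusted p = 2.84e-09, and an adjusted p = 0.388 with an estimated correlation. The falls included pvdA (-1.65 ± 0.18) and pvdH (-2.15 ± 0.24), enzymes of pyoverdine synthesis, and Pchl3084_3954 (-1.97 ± 0.22), a siderophore-interacting protein gene, and 36 of the 40 held under the 4 scalings. The 3 that rose were the bacterioferritin genes Pchl3084_4656 (bfr, 1.66 ± 0.23) and Pchl3084_5292 (bfr, 0.84 ± 0.24), which encode iron storage proteins, and btuB, a putative vitamin B12 receptor gene (0.89 ± 0.31).

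Of 22 oxidative stress genes, 12 fell and 3 rose (the same counts adjusted over the list alone), with a median of -0.61; camera gave an adjusted p = 0.00151, and an adjusted p = 0.388 with an estimated correlation. katG (-2.35 ± 0.20), a catalase-peroxidase gene, and trxB (Pchl3084_0942, -1.58 ± 0.19), a thioredoxin reductase gene, fell beside katB and ahpF, and all 12 falls held under the 4 scalings. sodB, an iron superoxide dismutase gene, rose by 0.94, and 2 of the 3 rises held. Prophage and tailocin genes, the latter encoding phage-tail-like particles that kill related bacteria, fell in 21 of 40 cases and rose in 1 (22 and 1 adjusted over the list alone), with a median of -1.13; camera gave an adjusted p = 2.13e-07, and an adjusted p = 0.443 with an estimated correlation. Examples were the baseplate gene Pchl3084_1198 (-1.45 ± 0.31), the holin gene hol (-1.41 ± 0.32) and the tail gene Pchl3084_1228 (-1.91 ± 0.52), and all 21 falls held under the 4 scalings. Of 45 type VI secretion genes, which encode a contractile injection machine, 25 fell and 1 rose (26 and 1 adjusted over the list alone), with a median of -0.59; camera gave an adjusted p = 2.13e-07, and an adjusted p = 0.388 with an estimated correlation. hcp1 (-1.31 ± 0.32) and tssC1 (-1.54 ± 0.41), structural parts of the tube and sheath, fell with tagT (-1.42 ± 0.38) and tagQ (-1.14 ± 0.34). Of the 25 falls, 21 held under the 4 scalings. Another gene of the Hcp1 family, Pchl3084_0233, did not pass (-0.42 ± 0.43; limma adjusted p = 0.112). Its level was far higher, at 8645 and 7748 RPKM in wild type, against 136 and 125 RPKM for hcp1.

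Of 54 ribosomal protein genes, 50 rose and 1 fell (51 and 1 adjusted over the list alone), with a median of 0.64 after median-ratio scaling, of 0.059 with quantile normalization and of -0.042 as deposited, where it lay 0.62 above the median relative to all genes. Camera gave an adjusted p = 9.7e-16, lost with quantile normalization (adjusted p = 0.430) and with an estimated correlation (adjusted p = 0.388). Only 5 of the 50 rises held under the 4 scalings; rpmE (Pchl3084_0441, 1.11 ± 0.27) and rpmF (1.02 ± 0.26) were among them, whereas rplL (0.96 ± 0.21) was at 0.36 and not called with quantile normalization. The gene that fell was the other copy of rpmE (Pchl3084_4695, -0.60). Of 43 genes of the TCA cycle and respiration, 34 rose and 3 fell (35 and 4 adjusted over the list alone), with a median of 0.52 and of -0.15 as deposited; camera gave an adjusted p = 1.27e-08, and an adjusted p = 0.388 with an estimated correlation. sdhA (0.86 ± 0.19) and sdhD (0.92 ± 0.19), subunits of succinate dehydrogenase, rose, and 15 of the 34 rises held under the 4 scalings. The 3 falls were fumC (Pchl3084_0906, -2.27 ± 0.35), acnA (-0.95) and icd (Pchl3084_3686, -0.69), and these held. Of 29 chaperone and protease genes, 16 rose and 1 fell (17 and 2 adjusted over the list alone), with a median of 0.37, of 0.0097 with quantile normalization and of -0.30 as deposited. Camera gave an adjusted p = 0.00465, lost with quantile normalization (adjusted p = 0.973), as deposited (adjusted p = 0.0787) and with an estimated correlation (adjusted p = 0.448). Under the 4 scalings 1 of the 16 rises held. groS, a chaperonin gene, was at 0.65 ± 0.23 and at -0.031 as deposited, and clpP (Pchl3084_3012), a protease subunit gene, fell by 1.43 on the log2 scale.

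Of 78 pilus genes, 11 fell and 0 rose (7 and 0 adjusted over the list alone), with a median of -0.23. Over all 5960 tested genes 846 fell, which is about the same share. Camera gave an adjusted p = 0.00635, lost with quantile normalization (adjusted p = 0.183), as deposited (adjusted p = 0.0769) and with an estimated correlation (adjusted p = 0.388). Pchl3084_4518 (-0.72 ± 0.22), a pilus secretin gene, and Pchl3084_4519 (-0.57 ± 0.24), a pilus assembly lipoprotein gene, were among those that fell, but neither was called when either wild-type library was left out; 7 of the 11 falls held under the 4 scalings. The other lists did not pass camera after median-ratio scaling. Of 52 amino acid catabolism genes, 10 rose and 22 fell (13 and 23 adjusted over the list alone; camera adjusted p = 0.107), among them gcdH (-1.40 ± 0.23), mmsA (-1.38 ± 0.28) and hmgA (0.93 ± 0.18). Of these calls 4 and 22 held under the 4 scalings, and the list passed with quantile normalization (camera adjusted p = 0.000446), with rRNA and tRNA genes left out (camera adjusted p = 0.0421), at a mean RPKM of at least 10 (camera adjusted p = 0.0192) and without wild-type replicate 1 (camera adjusted p = 0.0276). Of 79 amino acid and peptide transport genes, 17 rose and 7 fell (the same counts adjusted over the list alone; camera adjusted p = 0.808), for example Pchl3084_0342 (1.13 ± 0.25) and Pchl3084_2097 (-0.74 ± 0.21), and 12 and 6 held under the 4 scalings. Of 67 multidrug efflux genes, 10 rose and 14 fell (the same counts adjusted over the list alone; camera adjusted p = 0.126), and Pchl3084_3347 (-2.27 ± 0.24), next to Pchl3084_3346, was among the latter; 2 rises and 12 falls held. Of 49 outer membrane and cell envelope genes, 15 rose and 5 fell (15 and 9 adjusted over the list alone; camera adjusted p = 0.722), with the porin gene oprO at 1.22 ± 0.27; 9 rises and 3 falls held. Of 24 low-oxygen respiration genes, 10 rose and 2 fell (10 and 4 adjusted over the list alone; camera adjusted p = 0.126), with the oxidase gene ccoN (Pchl3084_1908) at 0.87 ± 0.23. Of these, 5 rises and 2 falls held, and the list passed with rRNA and tRNA genes left out (camera adjusted p = 0.0327) and at a mean RPKM of at least 10 (camera adjusted p = 0.0141). Of 74 flagellar and chemotaxis genes, 7 rose and 5 fell (6 and 4 adjusted over the list alone; camera adjusted p = 0.532), and the motility sigma factor gene fliA was at 0.40 ± 0.18 and at -0.27 as deposited. Under the 4 scalings 0 of the 7 rises and 3 of the 5 falls held. Of 80 exopolysaccharide and biofilm genes, 4 rose and 11 fell (2 and 8 adjusted over the list alone; camera adjusted p = 0.109), with algR at -0.37 ± 0.19. Of these, 1 rise and 6 falls held, and the list passed with rRNA and tRNA genes left out (camera adjusted p = 0.0327) and when scaled to reads outside rRNA genes (camera adjusted p = 0.0293). Of 5 carbon catabolite control genes, 2 rose and 0 fell (3 and 0 adjusted over the list alone; camera adjusted p = 0.134), namely rpoN (0.75 ± 0.26) and cbrB (0.30 ± 0.19, and -0.38 as deposited), of which rpoN held. Of 16 transposase and mobile element genes, 1 rose and 0 fell (0 and 0 adjusted over the list alone; camera adjusted p = 0.748); the rise did not hold.

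**Figure D3:**
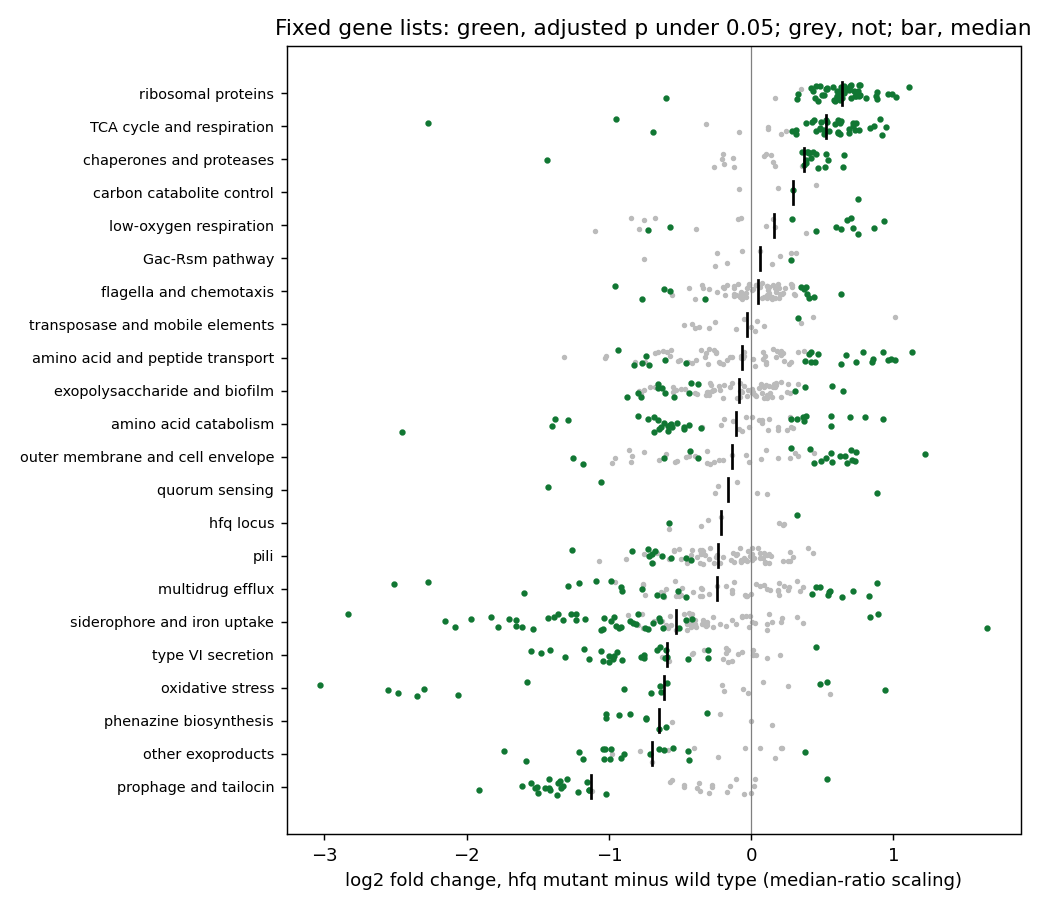
Log2 fold change of hfq mutant over wild type after median-ratio scaling for the members of the 22 tested lists, 1 dot per gene; green dots passed limma at an adjusted p below 0.05, grey dots did not, and black bars are list medians. The medians run from -1.13 for prophage and tailocin genes to 0.64 for ribosomal proteins, whose median is -0.042 as deposited.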

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

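The scaling to reads outside rRNA genes and the alternatives run on top of median-ratio scaling were chosen after seeing the data. As deposited, 1 gene was called higher and 12 lower. Median-ratio scaling gave 1195 and 846, quantile normalization 822 and 733, leaving out rRNA and tRNA genes 691 and 1594, and reads outside rRNA genes 707 and 1286. A pseudocount of 5 gave 2 higher, limma without the trend 7 and 89, limma with a robust prior 0 higher, the count model on recovered reads 2 and 84, an adjusted p below 0.10 20 lower, and an unadjusted p below 0.05 19 and 325. Leaving out 1 library gave 0 to 295 higher and 0 to 5545 lower; the lone library is then assumed to vary like the other strain, and 0 passed without either wild-type library. After median-ratio scaling the leave-one-out ranges were 158 to 1790 and 240 to 1465, and a change of at least 2-fold left 93 and 272. The 4 scalings shared 519 higher and 651 lower. No label ties a replicate number to a shared day or batch. The differences between replicates 1 and 2 correlated at -0.39 across genes between strains, so they were partly shared in crossed order. As deposited, hfq mutant replicate 1 correlated at 0.956 with wild-type replicate 2 and at 0.952 with wild-type replicate 1. For hfq mutant replicate 2 these values were 0.963 and 0.967. The rRNA share was the higher of its strain in wild-type replicate 2 and in hfq mutant replicate 1. The cause was not tested, and a block pairing equal replicate numbers cannot remove a difference shared in crossed order. With the replicate block 0 genes were called in either direction as deposited, and 840 and 598 after median-ratio scaling, of which 825 and 587 were called without it.

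Past camera were 8 lists as deposited and 13 with rRNA and tRNA genes left out. With an estimated correlation 0 passed on either scale, and fry passed 0 as deposited. The hfq log2 fold change of -0.99 became -0.64, -0.51 and -0.48, past the threshold, with quantile normalization, with rRNA and tRNA genes left out and with reads outside rRNA genes; leaving out 1 library gave -1.70 to -0.27. Of the alternatives for the named genes after median-ratio scaling, 1491 kept direction and side of the threshold, 154 kept only the direction, 14 newly passed and 15 changed sign. Those 15 did so as deposited, where the median gene lay at -0.67. It lay at -0.19 when scaled to reads outside rRNA genes and at -0.22 with rRNA and tRNA genes left out. So part of the shift remained once rRNA reads were taken out of the totals, and its cause was not tested. Called after median-ratio scaling were hflK -0.35, gacA -0.39, cbrB -0.38, groS -0.031, hslV -0.16, grpE -0.14, hscA -0.15, cheY -0.23, fliA -0.27, Pchl3084_2399 -0.043, tolB -0.056 and tnpT -0.33. Not called on either scale were hflX -0.46, hflC -0.45 and Pchl3084_5919 -0.44 (all values as deposited). Lists past camera on neither scale also changed direction, never past the threshold (camera adjusted p in each case). These were the Gac-Rsm pathway at a mean RPKM of at least 10 (0.935), with quantile normalization (0.650), with rRNA and tRNA genes left out (0.712) and with reads outside rRNA genes (0.837); flagella and chemotaxis under the same 3 scalings (0.650, 0.632 and 0.744); and mobile elements as deposited (0.866). The direction changed without hfq mutant replicate 2 for amino acid and peptide transport (range over the libraries left out 0.587 to 0.973) and mobile elements (0.517 to 0.889), and without hfq mutant replicate 1 for the hfq locus (0.305 to 0.827). Of 105 named genes, 25 no longer passed without wild-type replicate 1 and 23 without wild-type replicate 2, among them miaA, csaR, iopB, Pchl3084_0010, fliA, groS, algR, Pchl3084_4518 and Pchl3084_4519 in both cases. The cause of the other differences was not tested. Depth limits hfq mutant replicate 1 most, with a median of 185 reads per recovered gene.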

Other observations

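All tests of explanations below, and the genes of the next paragraph, were chosen after the values had been seen.

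Beside Pchl3084_1488 and Pchl3084_1492, the neighbouring genes iaaM (2.03 ± 0.29; limma, Benjamini-Hochberg adjusted p = 0.000644) and iaaH (1.98 ± 0.24; limma adjusted p = 0.000447) rose after median-ratio scaling. They encode a tryptophan monooxygenase and indoleacetamide hydrolase, which together turn tryptophan into indole acetic acid, and mtr, a tryptophan transporter gene next to them, rose by 1.84. trpA (1.37) and trpB (1.51) rose, while trpF stood at 0.050 (limma adjusted p = 0.653). The genes of another tryptophan route, kynA (0.13) and kynB (0.055), did not pass. Among small RNAs, phrS rose (2.17 ± 1.19; limma adjusted p = 0.0211), by 2.93 over wild type in hfq mutant replicate 1 and by 1.41 in hfq mutant replicate 2. prrF1, which represses iron-using genes when iron is scarce, fell (-0.73 ± 0.34; limma adjusted p = 0.0133), but its sister RNA prrF2 did not pass (-0.39 ± 1.07; limma adjusted p = 0.501) and lay at 0.24 in hfq mutant replicate 1 and at -1.01 in hfq mutant replicate 2. prrF1 stood at 19.7 and 16.1 RPKM in wild type and at 4.21 and 9.70 RPKM in hfq mutant replicates 1 and 2. At this level a small RNA has few reads, so its counting error may be larger than the interval shows. iaaM, iaaH, phrS and prrF1 kept their calls under the 4 scalings. katA (Pchl3084_5293, -2.30 ± 0.34) lies next to the bfr gene Pchl3084_5292 in the gene table, which rose. The manganese superoxide dismutase gene sodA1 (-2.06 ± 0.26) fell, as did fumC (Pchl3084_0906, -2.27), which lies close to it by locus tag.

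The first pattern is the low level of most genes in hfq mutant replicate 1, whose deposited log2 ratio to hfq mutant replicate 2 had a median of -1.26 over 5859 genes. Scaled to reads outside rRNA genes that median was -0.015, consistent with rRNA reads being counted in the library total. Loss of Hfq is argued against, since hfq mutant replicate 2 lay at -0.073 against the wild-type mean, where hfq mutant replicate 1 lay at -1.33. Why depletion of rRNA left more in that library was not tested.

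The second pattern is the level of the small RNAs RsmX, RsmY and RsmZ, which bind the translational regulators RsmA and RsmE. rsmY stood at 101 and 140 RPKM in wild type, at 3173 in hfq mutant replicate 1 and at 210 in hfq mutant replicate 2, and did not pass (limma, Benjamini-Hochberg adjusted p = 0.149). On the scaled log2 scale hfq mutant replicate 1 lay above replicate 2 by 3.05 for rsmX, 5.17 for rsmY and 4.00 for rsmZ. The SD of that difference over all genes was 0.53. These RNAs were picked for their high level in hfq mutant replicate 1. Their difference between the replicates therefore cannot decide whether loss of Hfq was the whole cause. The level in hfq mutant replicate 2 also lay above the wild-type mean, by 0.12 for rsmX, 0.86 for rsmY and 1.24 for rsmZ. For srpB, the signal recognition particle RNA, it lay above by 1.45. More short RNA kept in hfq mutant replicate 1 may contribute: 65 of 73 tRNA genes were higher there than in replicate 2, with a median of 0.67 (quartiles 0.31 and 1.09), but the 99 coding genes of at most 200 bases had a median of 0.10. Other small RNAs went both ways between the same libraries, with srpB at 3.20, phrS at 1.52 and the t44 RNA Pchl3084_1156 at 1.40, but the 6S RNA Pchl3084_5688 at -1.58, rnpB at -0.16 and ssrA at 0.16, so the question stays open.

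The third pattern is the hfq transcript, at 80.9% of wild type (95% interval 68.4 to 95.6) after median-ratio scaling in the libraries labelled hfq mutant. This is a log2 fold change of -0.31, which lay between -0.48 and -0.64 under the other scalings and at -0.99 as deposited. The interval does not cover the choice of scaling. Wild-type RNA in these libraries as the only source of the hfq transcript would leave no gene further below wild type than hfq. Yet 285 genes lay below it, interval against interval, and katB was at 12.2%. The bound first set for this test was 5% of genes, or 298, which 285 does not reach and by which this explanation would have stayed open. It was replaced after the result was seen by 2.5%, or 149, chosen as the one-sided error of a 95% interval. Neither bound is the share that error alone would give, since the count asked for intervals that do not overlap, all against the same hfq interval. So the bounds decide nothing. The explanation allows no gene below hfq, and the 285 genes below hfq argue against it. An exchange between 1 wild-type and 1 mutant library is argued against by the correlation of 0.972 between the libraries labelled hfq mutant, above the highest value across strains, 0.967. An exchange of both pairs, or another strain in both libraries labelled hfq mutant, would leave these correlations as they are and was not tested. Values of phz genes per library had been planned beside hfq, because the design text names a ZN mutant. phzB stood at 1931 and 1856 RPKM in wild type and at 549 and 912 RPKM in the libraries labelled hfq mutant. What level a ZN mutant would have was not set beforehand, so these values decide nothing. A mutation that leaves much of the transcript, such as a small deletion or an insertion, may account for the hfq level found and stays open. Values per gene do not show which part of hfq was read.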
